A study of Homo sapiens with 6 samples.

How the data were processed

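RNA of 3 samples of parental A549 cells and 3 of A549-RR was measured on 6 one-colour arrays, all on 1 slide scanned once. The deposited scanner files give spot intensity on a linear scale. Per the file headers and the submitters' processing notes, the authors extracted them with Agilent Feature Extraction 11.0.1.1, which subtracts the background and detrends the signal within each array; the files hold no normalization between arrays. A deposited table of log2 values of the same arrays was also used. Its processing is not given in the sources used here. From the values, its columns have nearly the same quartiles, with medians of 5.79. Each correlates best with its own array (r of 0.996 to 0.998 across probes). Scale and direction were settled from the values, and the centring step is not stated. A fit on this table called 2479 probes, against 2478 after quantile normalization of the processed signal. These 2 alternatives are thus nearly the same and are not independent checks.

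Each array held 62921 spots. The analysis kept 60496 probes of the array maker's own identifier series, with 1 spot each, and 50 catalogue probes with 10 spots each. It left out 68 control probes and 182 probes with other identifiers. Outlier spots, 27 to 48 per array, were removed and spots of a probe averaged on the log2 scale. The 49 catalogue probes whose accession matched 1 symbol were named through the RefSeq gene table of assembly GCF_000001405.40 (GRCh38.p14), used for names only; 1 did not match. All other probes have no gene name in the sources used here, and their identifiers were not read for meaning. Each named gene therefore rests on 1 probe. Spots of a named probe had a median SD of 0.04 log2 units within an array.

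Log2 processed signal was set relative to the 75th percentile of each array. A probe was tested where it was well above background on all 3 arrays of at least 1 line, which kept 44239 of 60546 probes; 4 named genes, CFTR, ZAP70, SAA4 and CD69, were not tested. A549-RR was compared with the parental line by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no block), with Benjamini-Hochberg adjustment over all tested probes. A positive log2 fold is higher in A549-RR. On simulated data with the means and spreads of 44192 probes, the same fit recovered 49% of probes changed 2-fold and 91% of those changed 4-fold, with 4 false calls among 144. The simulation drew independent noise for each probe, with an SD pooled over both lines, and changed 100 probes at each fold. The real probes vary together and spread more in A549-RR, so these figures give no error rate for the real data.

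The comparison, the 34 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule takes up to 12 genes in each direction with an adjusted p under 0.05, a fold of at least 2, lines that do not overlap and signal above background on all 6 arrays; from each list it takes up to 4 members that passed, or 6 for 2 of the lists, and otherwise the 2 members with the highest mean signal. It gave 11 genes. The other 18 genes given with values, ITGB3BP, CCNA2 and CENPE among them, were chosen after their values were seen. As the lists had too few measured members, the named genes were also sorted into groups by known function. The groups were fixed once the gene names were known and before the values were seen, and the choice to test 5 of them, all with at least 5 tested members, by camera came after. One of the 5 holds genes with no common function; it shifted up with an adjusted p of 0.00317, and an adjusted p of 0.400 with an estimated correlation, and is given no theme.

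Alternatives were quantile normalization, centring on the array median, a normexp background correction with an offset of 50, the deposited log2 table, 2 other filters on dim probes, the replicate number as a block, eBayes with trend and robust variances, variances without moderation, and leaving out each array. The normexp correction used the median spot signal, since the mean signal is not among the columns used here. The slide row as a block, a fit within slide row 1, and a covariate for the gap between 2 control probes of PGK1, whose names end in 3 and in 5, were added after seeing the data.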

Results

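RNA abundance was measured on 6 one-colour arrays of A549, an established human lung cancer cell line of epithelial origin, and of a radioresistant derivative, A549-RR. Per the labels, A549-RR had been raised by repeated exposures of 4 Gy to a total of 60 Gy, followed by further culture. Total RNA of 3 samples of the parental line and 3 of A549-RR was labelled and hybridised, 1 sample per array. The labels do not say whether the samples of a line came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The 75th percentile of the processed signal lay between 281 and 359 on the 6 arrays, between 73.4% and 78.2% of probes were well above background, and no spot was saturated. The number of arrays limits the precision. The comparison asks which transcripts differ between the radioresistant line and its parent.

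Among 45 named genes that could be tested, 4 rose and 3 fell in A549-RR at an adjusted p under 0.05. RND3 rose 3.39-fold, with a log2 fold of 1.76 ± 0.28 (SE, n = 3 arrays per line) and an adjusted p of 0.0104 by limma. SPP1, which encodes the secreted glycoprotein osteopontin, rose 3.18-fold, with a log2 fold of 1.67 ± 0.20 and an adjusted p of 0.00363 by limma. NMI, an interferon-inducible partner of MYC-family proteins, rose 2.61-fold, and LMO2, a transcriptional cofactor best known from blood cell development, rose 2.15-fold. The log2 fold of LMO2 was 1.11, and 0.70 after normexp, which is under a 2-fold rise. PIMREG, a mitotic regulator also known as FAM64A, was 2.74-fold lower in A549-RR, with a log2 fold of -1.45 ± 0.13 and an adjusted p of 0.00107 by limma. KIF20A, a kinesin required for cytokinesis, was 2.08-fold lower, and ITGB3BP, which encodes the kinetochore protein CENP-R, was 1.89-fold lower. In each of these 7 genes all 3 arrays of one line lay above all 3 of the other, as in 16 of the 45 tested genes in all. The 7 genes were called on the same arrays, so this adds no further support.

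**Figure D1:**
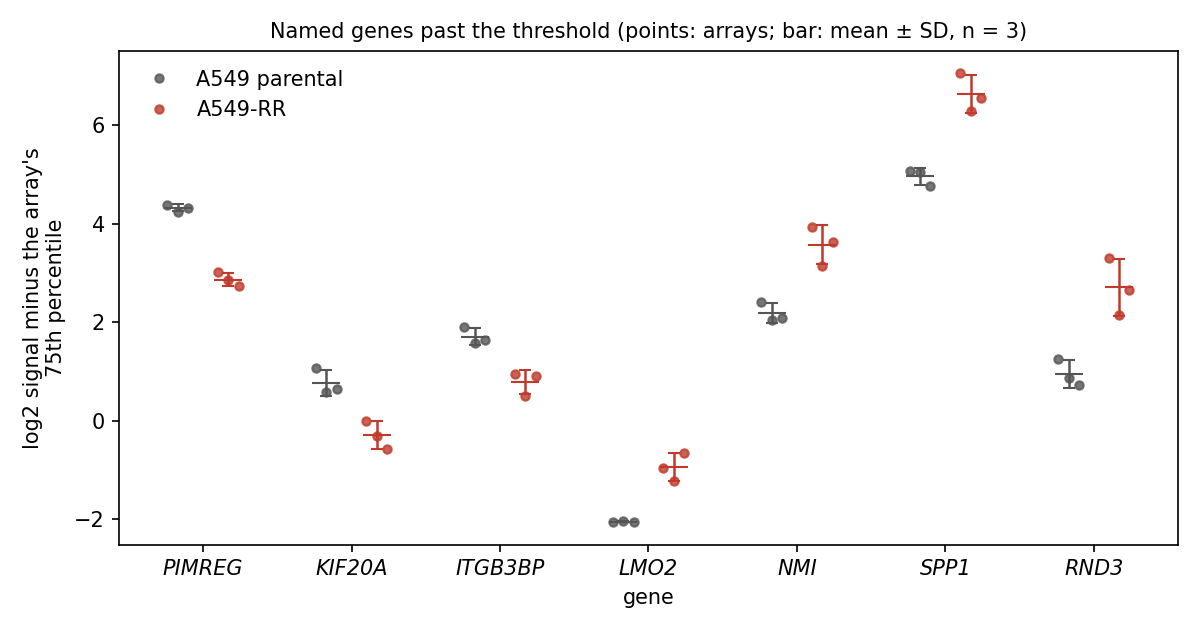
Log2 processed signal minus the array's 75th percentile for the 7 named genes with an adjusted p under 0.05; points are single arrays, and bars are the mean ± SD of 3 arrays per line. The 3 arrays of one line lie apart from the 3 of the other in every gene shown, with LMO2 at -2.05 ± 0.01 in the parental line and -0.94 ± 0.29 in A549-RR.

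All 3 named genes that fell belong to a group of 7 mitosis and kinetochore genes. The other 4 did not pass the test. CCNA2, the cyclin A gene of S phase and mitotic entry, had a log2 fold of -1.01 ± 0.25 and an adjusted p of 0.0538 by limma, and CENPE, a kinetochore motor, had one of -0.78 ± 0.24. CENPQ stood at -0.42 ± 0.25, and SPDL1, an adaptor that brings dynein to the kinetochore, at 0.39 ± 0.31 in the opposite direction. CCNA2 passed in 4 and CENPE in 3 of 17 alternative analyses. The group as a whole shifted down against all tested probes in camera with a preset correlation of 0.01 (adjusted p = 0.000162 over 5 groups). The shift did not pass with an estimated correlation of 0.73 between members (adjusted p = 0.400). Of the list of G2 and mitosis genes fixed before the data were examined, 3 members were measured, CCNA2, CENPE and KIF20A; 1 passed over all probes, and 3 passed when adjusted over the list alone, with adjusted p-values of 0.00498, 0.0117 and 0.00143 by limma.

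None of the 5 DNA replication and chromatin assembly genes passed the test, and 4 of them had a lower mean in A549-RR. DSCC1, a subunit of a clamp loader complex, had a log2 fold of -0.65 ± 0.23, CHAF1B, a subunit of chromatin assembly factor 1, one of -0.59 ± 0.17, and PRIM1, the catalytic subunit of DNA primase, one of -0.57 ± 0.17. WDHD1 stood at -0.24 ± 0.32 and DTL at 0.09 ± 0.28. DSCC1 passed in 2 and PRIM1 in 1 of the 17 alternative analyses. The group's shift had an adjusted p of 0.0456 in camera with the preset correlation, and an adjusted p of 0.447 with an estimated correlation. The preset call was also lost under quantile normalization (adjusted p = 0.0565), after normexp (0.0600), on ranks (0.0569), and without parental replicate 1 (0.185), A549-RR replicate 2 (0.314) or A549-RR replicate 3 (0.136). PRIM1 was the 1 measured member of the fixed list of G1/S and replication genes, so that its p adjusted over the list alone is its unadjusted limma p, 0.00905; its adjusted p over all probes was 0.100.

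None of the 7 DNA repair and DNA end processing genes passed; 5 had a lower and 2 a higher mean in A549-RR. BRCA1, which acts in homologous recombination, had a log2 fold of -0.44 ± 0.26, the recombination factor RAD54B one of -0.10 ± 0.33, the exonuclease gene EXO1 one of -0.30 ± 0.30 and SMC6, which passed in 1 of the 17 alternative analyses, one of -0.60 ± 0.29. ABRAXAS1 stood at -0.11 ± 0.15, and the helicase gene WRN, at 0.24 ± 0.26, and the chromatin remodeller gene SMARCAD1, at 0.55 ± 0.29, had the higher means. The camera shift of the group had an adjusted p of 0.588 with the preset correlation and of 0.839 with an estimated correlation of 0.93. With the preset correlation, the only one used in the other alternatives, it passed downward without A549-RR replicate 1 (adjusted p = 0.0127) and with the gap between the PGK1 control probes as a covariate (4.93e-06). The fixed list of double-strand break repair had 3 measured members, BRCA1, EXO1 and RAD54B, and 0 passed either over all probes or adjusted over the list alone; limma gave them unadjusted p-values of 0.122, 0.342 and 0.766.

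Of 5 tested genes for secreted and extracellular matrix proteins, SPP1 alone rose and the other 4 did not pass. The group's upward shift in camera had an adjusted p of 0.126 with the preset correlation and of 0.400 with an estimated one. LOXL2, for a collagen and elastin cross-linking enzyme, had a log2 fold of -0.44 ± 0.15, SERPIND1, for heparin cofactor II, one of -0.17 ± 0.17 and COL13A1, for a transmembrane collagen, one of 0.34 ± 0.15. LOX, for another such enzyme, was well above background on all 3 A549-RR arrays and 1 parental array, so that its fitted log2 fold of 0.56 ± 0.18 is no firm estimate; it was 0.05 after normexp, and it passed in 1 of 16 alternative analyses. LOX was the 1 measured member of the fixed list of mesenchymal markers, and its p adjusted over the list alone is its unadjusted limma p, 0.0152, against an adjusted p of 0.139 over all probes. Of 3 tested genes of the lymphoid lineage, LMO2 rose and TCF7, a transcription factor of Wnt signalling and T cells, had a log2 fold of 0.42 ± 0.14; the third, at -0.02, did not pass either. TCF7 was the 1 measured member of the fixed list of Wnt targets, with an unadjusted limma p of 0.0176, which adjusting over the list alone leaves as it is, and an adjusted p of 0.151 over all probes. CD69 and ZAP70 were not well above background on any array. The zinc finger gene ZNF195 had a log2 fold of 0.97 ± 0.25 and an adjusted p of 0.0643 by limma, and passed in 3 of the 17 alternative analyses. Groups of chromatin regulators, of ribosome biogenesis and translation genes and of metabolic enzymes gave 0 calls among 4, 4 and 4 tested genes.

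**Figure D2:**
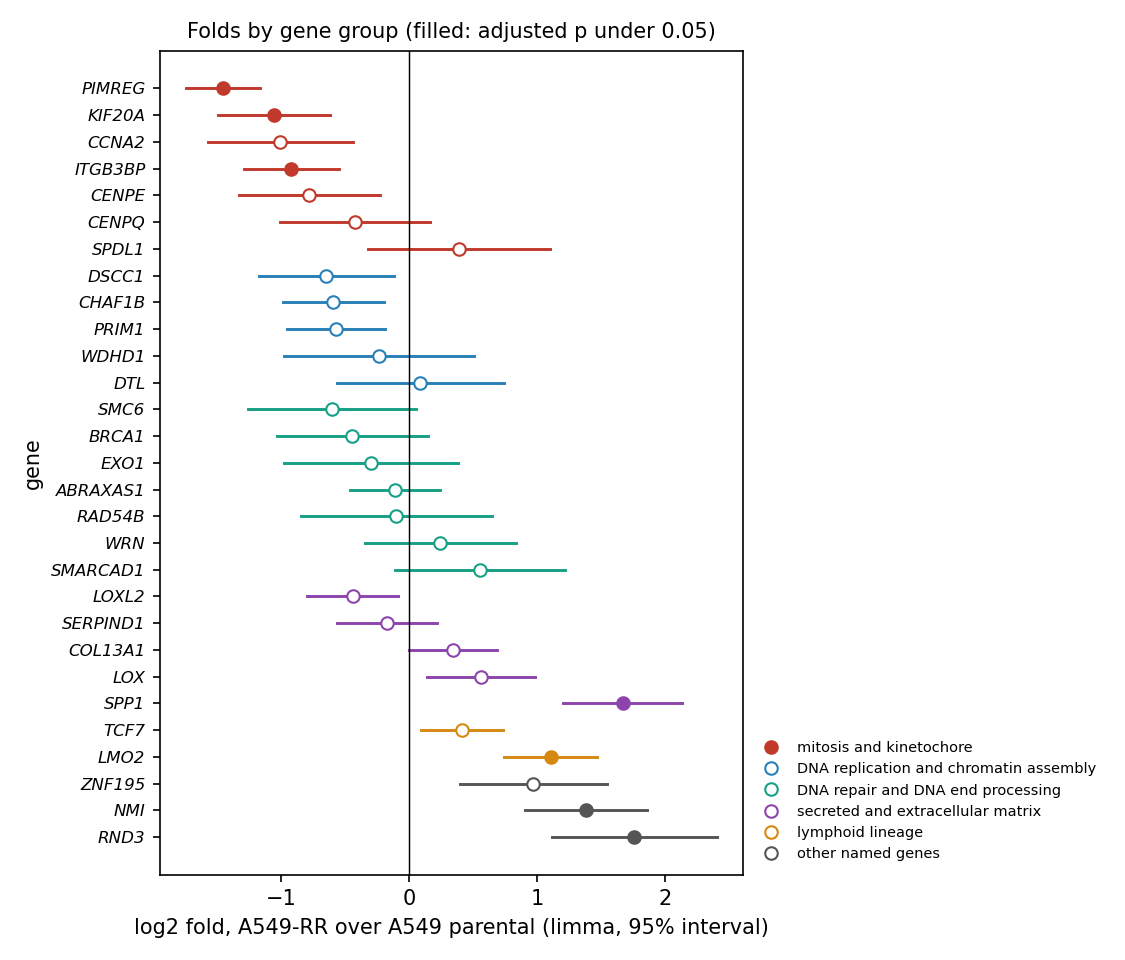
Log2 fold of A549-RR over the parental line with its 95% interval from limma, for the genes described, coloured by group; filled points have an adjusted p under 0.05. PIMREG, at -1.45, and RND3, at 1.76, are the lowest and the highest points.

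Over the whole array, 2601 of 44239 tested probes differed between the lines at an adjusted p under 0.05 by limma, 1468 higher and 1133 lower in A549-RR. At a fold of at least 2, 719 probes were higher and 396 lower. The balance was not stable: without A549-RR replicate 1, 1045 probes were higher and 1233 lower, and 538 and 519 at a fold of at least 2. The lines did not overlap in 23.6% of tested probes. For a single probe chance gives 10%. Probes vary together, so by chance the share over all probes can lie far from that figure. The files used here pair nearly all of these probes with no gene name, so that 0 of the 34 fixed lists reached the 5 measured members needed for a test, and probes could not be split into coding and noncoding. The largest rise among probes well above background on all 6 arrays was 26.5-fold, of ASHG19LNC1A100076331V5, and the largest fall 5.20-fold, of ASHGV40034341V5. The scaled log2 signal of the rising probe was low in the parental line, at -3.77 ± 0.50 (mean ± SD). The size of its rise may thus depend on the background correction. After normexp the called probes had a median ratio of 0.71 to their main folds, and the fold of this probe is not given for that setting. On all 3 A549-RR arrays and no parental array, 86 probes were well above background, 73 of them with an adjusted p under 0.05, and 174 were so on all 3 parental arrays and no A549-RR array, 82 of them with an adjusted p under 0.05.

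The lines separated along the first principal component, which held 52.3% of the variance. Within A549-RR its score was 58.5, 46.5 and 14.0 for replicates 1, 3 and 2, whose PGK1 gaps were 7.58, 7.63 and 7.73. Parental replicate 1, in slide row 1 with a gap of 7.72, lay nearest A549-RR at -26.6. Parental replicates 2 and 3, at -46.0 and -46.4, had gaps of 7.84 and 7.80. Parental replicate 1 and A549-RR replicate 2 share the slide row and nearly the same gap, yet score -26.6 and 14.0. Row and gap thus do not account for the distance between these 2 arrays. With 1 array of each line, this does not separate the line from the gap or the slide row for the other arrays. The A549-RR arrays were less alike than the parental ones. Across probes, which are not independent replicates, r was 0.989 to 0.993 between A549-RR arrays and 0.996 to 0.997 between parental arrays. The median SD of a probe was 0.20 on the log2 scale in A549-RR and 0.12 in the parental line. All A549-RR arrays and parental replicate 1 lay in slide row 1 and the other 2 parental arrays in row 2; with the slide row as a block 157 probes and 1 named gene, PIMREG, passed. All 2601 called probes kept their sign in that fit, with a median absolute log2 fold of 0.85 against 0.92, while their median SE rose from 0.16 to 0.22. Row 2 holds parental arrays alone, so the fold in that fit is against parental replicate 1. That array also helped to call these probes, so the kept signs are partly built in. Within row 1, where 1 parental array is assumed to vary like the A549-RR arrays, 48 probes and 0 named genes passed by limma (3096 probes at an unadjusted p under 0.05). With the PGK1 gap as a covariate, RND3 stood at a log2 fold of 0.92, NMI at 0.76, LMO2 at 0.92 and SPP1 at 1.23, and none of these 4 passed. The count of changed probes fell to 1627, 986 and 922 without parental replicates 1, 2 and 3, stood at 2278 and 1326 without A549-RR replicates 1 and 3, and rose to 4006 without A549-RR replicate 2; named genes passing ranged from 4, without parental replicate 3, to 11, without A549-RR replicate 1.

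**Figure D3:**
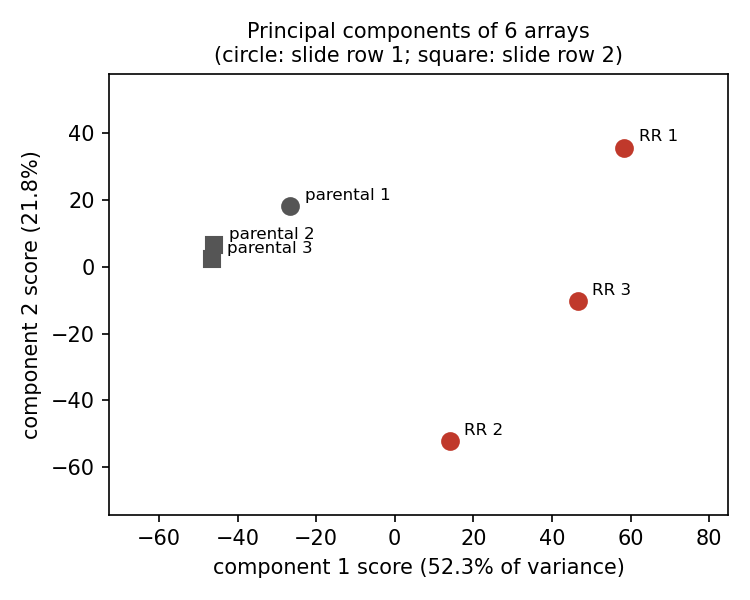
Scores of the 6 arrays on the first 2 principal components of the tested probes; colour gives the line and the marker the slide row. Component 1 holds 52.3% of the variance and places the parental arrays between -46.4 and -26.6 and the A549-RR arrays between 14.0 and 58.5.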

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

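The slide row, PGK1 and gene group fits were chosen after seeing the data; the others were planned. No called gene changed sign under any of the 17 alternatives run for it; PIMREG passed in 16 of them, SPP1, NMI and LMO2 in 13 each, RND3 and ITGB3BP in 12 and KIF20A in 9. Against 2601 changed probes, 1464 passed with no filter on dim probes, where more probes are tested, and 298 without moderation of the variances, where 135 changed at least 2-fold, against 1115, and 1 named gene passed. After normexp, 426 probes changed at least 2-fold, and the called probes had a median ratio of 0.71 to their main folds. That setting changed the spot signal, the background correction and the offset at once, so their parts are not told apart. The slide row as a block left 157 probes and 1 named gene, and row 1 alone 48 probes and 0 named genes, all probes at least 2-fold; both fits have fewer residual degrees of freedom, and the called probes kept their sign, with a median ratio of 0.94 to the unblocked folds. With the PGK1 gap as a covariate 236 probes, all at least 2-fold, and 3 named genes passed, 100 probes higher and 136 lower; without moderation 142 were higher and 156 lower. The covariate moved ZNF195 to 0.26 and BRCA1, RAD54B and SMC6 to -1.18, -1.08 and -1.43, and the group with no common function no longer passed (adjusted p = 0.896). Leaving out 1 array gave 922 to 4006 changed probes, 764 to 1413 of at least 2-fold and 4 to 11 named genes. With the replicate number as a block, 2694 probes, 1176 of at least 2-fold and 12 named genes passed; same-numbered arrays deviated together with r of 0.21, 0.12 and -0.13, and 3 of 6 arrays deviated most like their own number, so the numbers were not taken as pairs. The other alternatives gave 2233 to 2861 probes. Among 22 uncalled genes named, 8 changed sign: DTL to -0.36 with the slide row as a block and within row 1, to -0.72 with the PGK1 covariate, and between -0.22 and 0.31 without 1 array; SPDL1 to -0.16 by slide row, both ways, and -0.56 with the PGK1 covariate; RAD54B without parental replicate 1 (0.08) and A549-RR replicate 2 (0.20; range -0.48 to 0.20); WDHD1 without A549-RR replicate 2 (range -0.63 to 0.019); WRN by slide row, both ways (-0.0038), with the PGK1 covariate (-0.50) and without A549-RR replicate 1 (range -0.054 to 0.47); SMARCAD1 with the PGK1 covariate (-0.32); SERPIND1 with it (0.20) and without A549-RR replicate 1 (range -0.30 to 0.0058); ABRAXAS1 without A549-RR replicate 2 (range -0.23 to 0.031). The repair group turned upward, with adjusted p of 0.859 and 0.390, without parental replicate 1 and A549-RR replicate 2, and passed downward, with the preset correlation, without A549-RR replicate 1 (0.0127) and with the covariate (4.93e-06); with an estimated correlation its adjusted p was 0.839 over all arrays. Except where stated, the cause was not tested. The slide as a block was not run, as there is 1 slide; averaging a gene's probes does not apply to genes with 1 probe; the coding split and the fixed lists' tests were not run, and the deposited table lacks the named genes' probes. Signal over background limits 4 named genes that could not be tested.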

Other observations

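The tests of the slide row and of dividing cells on the mitosis genes were chosen after the result was seen. Among the named genes, the A549-RR arrays varied together. In 32 of 45 tested genes replicate 1 was highest, replicate 3 next and replicate 2 lowest, an order held by 19.97% of all tested probes, where chance gives 16.7%; the reverse order, held by 2 of the 45 genes, was the commonest over all tested probes, at 29.5%. In 42 of the 45 genes the SD was larger in A549-RR than in the parental line, and the median range over 3 arrays was 0.92 log2 units against 0.42. The gap between the PGK1 control probes was 7.58, 7.73 and 7.63 log2 units on A549-RR replicates 1, 2 and 3, and 7.72, 7.84 and 7.80 on parental replicates 1, 2 and 3. Over A549-RR replicates 1, 3 and 2 the gap thus rose. The 32 genes were picked because their signal fell in that order, so only the order of the gaps is free. Chance gives that order in 16.7% of cases, so the match says little. The lines' mean gaps differed by -0.14 (exact permutation p = 0.2, two-sided, where 0.1 is the smallest possible). Of 148 left-out probes tested, 2 were lower and 0 higher in A549-RR by limma (13 at an unadjusted p under 0.05). Of these 2, ERCC-00043_129 is a control spot, with a log2 fold of -0.79 and an adjusted p of 0.04999 by limma. A technical difference between the arrays was not tested through it.

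For the changed probes, the 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. Only 1 split, the real one, gave 2601 changed probes, 1115 of at least 2-fold or 7 named genes, and the highest other count was 0 in each case. Each other split mixes the lines, so any difference between them widens the spread within its groups, and the counts of 0 say little about chance. RNA integrity stays open. With the PGK1 gap as a covariate the folds of the called probes had a median ratio of 0.90 (quartiles 0.70 and 1.08). Most calls ended, as the median SE rose from 0.16 to 0.20 while the median absolute log2 fold went from 0.92 to 0.82. Single genes moved further, RND3 from a log2 fold of 1.76 to 0.92 and NMI from 1.38 to 0.76, so part of these rises may follow the PGK1 gap. The fit cannot decide the question, as the gap goes largely with the line and the slope rests on the spread within lines. Calling favours probes with little such spread for the size of their fold. That limits how far most of their folds could shrink, so the median ratio is partly built in. The gap between control probes of GAPDH differed between the lines by -0.03 (exact permutation p = 0.8, two-sided) and was not used as a covariate. An effect of the slide row stays open: probes called against the parental arrays of row 2 had a median ratio of 0.82 for their fold against the row 1 parental array, and 99.3% kept their direction, but row 1 holds 1 parental array, whose own spread is unknown. Both folds also share the A549-RR arrays, so the kept direction is partly built in. The radiation history of A549-RR, named by the design, stays open as an untested biological explanation.

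For the lower signal of mitosis and kinetochore genes, 3 of 10 splits, the real one included, gave a camera p with a preset correlation as small as the real 3.24e-05; the smallest other was 5.45e-06, and the splits are too few for a share under 0.05. Both other splits put A549-RR replicate 1 with parental replicate 1 and 1 further parental array. With the PGK1 gap as a covariate the median log2 fold of the 7 genes was -1.41. The covariate also lowered the folds of the other genes given with values, such as BRCA1 to -1.18 and RND3 to 0.92. LOXL2 and SERPIND1 alone moved up, to -0.24 and 0.20. The lower value is thus not particular to the mitosis genes and does not decide on RNA integrity. Against the row 1 parental array the median log2 fold of the 7 genes was -1.11, which rests on 1 array and leaves the slide row open. A lower share of dividing cells in the A549-RR cultures may be a candidate explanation, and would lower replication genes as well. The replication genes had a median log2 fold of -0.57. Their camera p was 0.357 with an estimated correlation, against 0.139 for the mitosis genes. With the preset correlation it was 0.0273, against 3.24e-05. A lower share of dividing cells thus stays open, as does a difference of the line itself.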
